A study of Mus musculus with 14 samples.

How the data were processed

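The series holds 14 arrays of RNA from sorted mouse skeletal muscle precursor cells, 5 from young (2 months), 4 from middle-aged (12 months) and 5 from aged mice (24 months), with ages, the sort gate and strain taken from the labels. Per the labels' protocols, myofibre-associated cells were freed by enzymatic digestion and mechanical dissociation, sorted by surface markers, extracted with Trizol, and labelled with the 3'IVT Express kit for hybridization to Affymetrix mouse arrays. Per the submitters' processing notes, the authors applied RMA, which corrects background, normalizes across arrays and summarizes probes into 1 value per probe set. The version of RMA, the array annotation and the genome build are not given in the sources used here. The deposited values are intensities on a linear scale (array medians 19.0 to 21.2), and their log2 was taken here without further normalization. No coordinates are given, since the files name no build.

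Of 45101 probe sets, 64 were control probe sets, 932 were annotated to several genes and 9160 to none, and these were left out of the gene tests. The platform annotation, dated 2016, gave the symbols, and 34741 of 34945 probe sets with 1 symbol matched a RefSeq table by Entrez identifier, with 0 symbols changed. A probe set was kept when it lay above the 40th percentile of its array (log2 3.79 to 3.96) on at least 4 of the 14 arrays, whatever the group, which left 23887. A gene was represented by its kept probe set with the highest mean over all arrays, which gave 13579 genes, 5993 of them with more than 1 kept probe set. Array data have no counting depth, and the number of arrays limits the precision.

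All 14 arrays entered 1 linear model per gene with the age group as the only factor, in limma 3.58.1 (R 4.3.3), with moderated two-sided tests and Benjamini-Hochberg adjustment over all genes, called at an adjusted p under 0.05. The comparisons were aged against young, middle-aged against young, aged against middle-aged, the late step minus the early step, and an F test over the 3 ages. Errors of log2 changes are limma's moderated standard errors, and errors of group means are SD. The 36 gene lists (713 symbols) cover satellite cell and myogenic genes, cell cycle, inflammation, interferon, antigen presentation, signalling and metabolic pathways, matrix, and markers of other cell types. Of these, 34 had at least 5 measured members and were tested with camera at a preset correlation of 0.01. Camera compares a list with all other genes; it was repeated with an estimated correlation, and fry, which tests whether a list's genes move on balance 1 way, was run as an alternative. Erythroid markers and sex-linked genes, with 4 measured members each, were not tested as lists.

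The groups, comparisons, tests, filter, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule named, per pairwise comparison, up to 12 largest rises and 12 largest falls among called genes whose groups did not overlap, up to 4 members per list with the smallest p, and a fixed set of sort, lineage and series-title genes. Where no gene passed, it named the 5 with the smallest p. Chosen only after the data were seen were the array sets and the alternatives built on them, the covariate of tenocyte markers, the list test of the late minus the early step, and Scx, Col1a1, Col1a2, Col3a1, Sparc, Atp2a1, Pygm, Scin and Ccdc12 as named genes. The array sets came from the first principal component of values centred by age group (31.5% of their variance), so the count of genes that differ between sets is not an independent test. A fit with the set as a term takes out much of that same spread, so its higher counts and smaller adjusted p are no independent support either.

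Alternatives changed 1 choice at a time: the dim filter, the choice of probe set, quantile normalization or median centring of arrays, the variance model, array weights, an RNA-quality covariate from the 3' minus 5' difference of the Gapdh and Actb control probe sets, a block by replicate number, a fit of only the groups compared, a fold minimum of 1.5, an unequal-variance test per gene, and each array left out in turn. The model was tested on simulated data with each gene's own spread, drawn independently for every gene and array. In 10 simulations with 200 changed genes, it recovered 65.6% of 2-fold and 97.6% of 4-fold changes in aged against young, with 5.70% false calls. In 20 simulations without a change, the median count was 0 and the highest 1. The simulations held no array sets and no correlation between genes, so they do not give the error rate on the real arrays. Single comparisons of array measures used exact two-sided permutation tests. Splits of the arrays into groups of the same sizes were drawn 100 at a time, after the results were seen, to ask how often other groupings give as large a count. GDF11 protein levels, cell function and treated animals are not analysed here, as the series holds arrays only.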

Results

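Expression was measured on 14 Affymetrix mouse arrays hybridized with RNA of sorted skeletal muscle precursor cells from C57BL/6 mice. The cells were myofibre-associated cells, freed by enzymatic digestion and sorted as carrying CD29 (encoded by Itgb1) and Cxcr4 and lacking CD45 (Ptprc), Ter119 and Sca-1 (Ly6a), a gate that enriches satellite cells, the stem cells of muscle. Young mice (2 months) gave 5 arrays, middle-aged mice (12 months) 4 and aged mice (24 months) 5. The series title concerns systemic GDF11 and muscle dysfunction with age, and no array carried a treatment label. The labels do not say whether each array came from a separate animal, so the p-values below measure only the spread between these samples, part of which may be technical. The median of the deposited intensities ran from 19.0 to 21.2 between arrays, and the number of arrays limits the precision.

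Transcripts of the myogenic lineage were present at every age. Pax7, the transcription factor that marks satellite cells, had a mean log2 value of 9.52 ± 0.45 (SD, n = 5) on young, 9.34 ± 0.38 (n = 4) on middle-aged and 9.02 ± 0.48 (n = 5) on aged arrays. Myod1, a myogenic commitment factor, stood at 11.21 ± 0.11, 10.84 ± 0.30 and 10.96 ± 0.30. Of the genes behind the sort, Itgb1 stood at 8.24, 8.39 and 8.12 and Cxcr4 at 8.60, 8.09 and 8.25, while both probe sets of Ptprc lay below the dim-signal filter on all 14 arrays. Gdf11, the ligand in the series title, lay above the 40th percentile on all 14 arrays, at 4.78 ± 0.16, 4.85 ± 0.25 and 4.56 ± 0.28. The cell cycle inhibitor Cdkn2a was below the filter on all 14 arrays, and neither Ly6a nor Mstn had a probe set of its own. None of Pax7, Myf5, Myod1, Myog, Itgb1, Cxcr4, Gdf11 and Spry1 passed the test in aged against young cells, where their log2 changes were -0.50, -0.57, -0.26, -0.79, -0.12, -0.35, -0.21 and -0.65. The Y-linked gene Eif2s3y was above the filter on every array, with age means of 8.32, 7.82 and 8.22.

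The arrays parted by age and also into a pair of sets that crossed the ages. The first principal component held 25.3% of the variance and separated young from older arrays, and the second, with 22.6%, separated 8 arrays (set 1: young 1, 3 and 4, middle-aged 2, 3 and 4, aged 1 and 2) from 6 (set 2: young 2 and 5, middle-aged 1, aged 3, 4 and 5). The sets were defined from the values after they were seen, and 2756 genes (20.3%) differed between them at equal age. The hybridization controls, added to each sample after labelling, were lower by a log2 difference of -0.72 in set 2 at equal age (exact permutation p = 0.0025, the smallest that 400 arrangements allow). Between ages, the 3' minus 5' difference of the Gapdh and Actb control probe sets, a sign of RNA quality, was 4.31 ± 0.54 on young, 3.85 ± 0.25 on middle-aged and 3.54 ± 0.51 on aged arrays (aged minus young -0.77, exact two-sided permutation p = 0.0714).

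**Figure D1:**
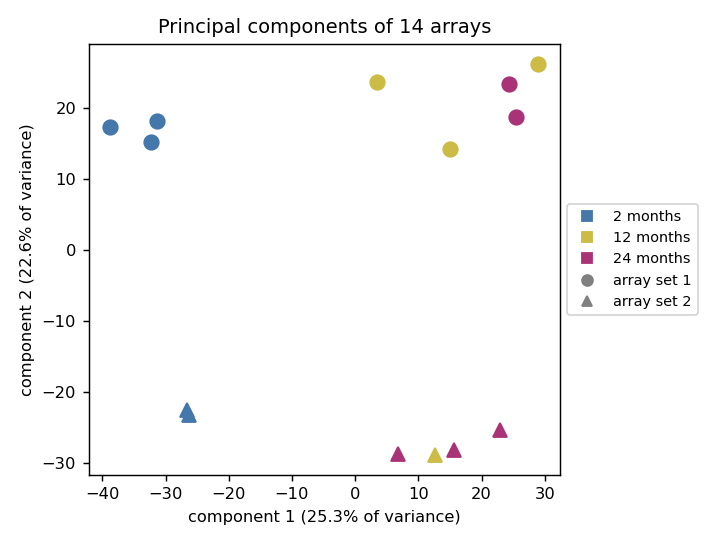
The first against the second principal component of log2 values of all tested genes, 1 point per array, coloured by age, with circles for array set 1 and triangles for array set 2. The 5 young arrays lie left of the other 9 on the first component (25.3% of the variance), and the sets lie apart on the second (22.6%).

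Aged against young cells is the widest age contrast of the design, which asks for transcriptional changes with age in muscle precursors. As lists, tenocyte markers, secreted inflammatory factors and interferon response genes rose, with calls that held at an estimated correlation. Mature myofibre transcripts rose and satellite cell identity genes fell at the preset correlation only (adjusted p = 0.0900 and 0.0988 with an estimated correlation). The largest rise was that of Mmp3 (Entrez 17392), the secreted matrix protease stromelysin, from 4.08 ± 0.77 (SD, n = 5) to 10.84 ± 1.05 (n = 5), a change of 6.76 ± 0.59 (SE) or 108-fold, although 3 of the 5 young arrays lay below the 40th percentile of their array and the fold against such a floor is imprecise. Il33, an alarmin cytokine, rose 15.2-fold (log2 3.93 ± 0.32), Tac1, the precursor of substance P, 21.3-fold (4.41 ± 0.46), and Ptgs2, the inducible prostaglandin synthase, 19.6-fold (4.29 ± 0.52). Every aged array lay above every young one for each of these genes.

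Tenocyte markers gave the strongest group change of the 34 lists tested. Of 9 measured members, 8 rose and 9 when adjusted over the list alone (adjusted p = 1.26e-17; adjusted p = 0.0167 with an estimated correlation), with a median log2 change of 2.52. The list mean went from 7.53 ± 0.57 on young to 10.02 ± 0.40 on aged arrays. Comp (Entrez 12845), a pentameric matrix protein of tendon and cartilage, rose 14.7-fold (3.88 ± 0.47), Thbs4, a thrombospondin of tendon, 9.47-fold (3.24 ± 0.38), Tnmd, the tendon membrane protein tenomodulin, 7.92-fold (2.98 ± 0.40) and Fmod, the collagen-binding proteoglycan fibromodulin, 3.63-fold (1.86 ± 0.23). The tendon transcription factor Scx, below the 40th percentile on all 5 young arrays, did not pass over all genes (0.98 ± 0.29, adjusted p = 0.0788). Further matrix genes were among the 12 largest rises: Cilp, of cartilage, rose 12.9-fold, Prg4, which encodes lubricin, 12.3-fold and Aspn, a small proteoglycan, 16.4-fold, with 4 of 5 young Aspn values below the 40th percentile. Cpxm2, Itgbl1 and Ctla2a rose 10.5-fold, 11.4-fold and 12.2-fold. Mndal, of a family of closely related interferon-inducible genes that probe sets may not tell apart, rose 30.1-fold from a level below the 40th percentile on 3 young arrays.

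**Figure D2:**
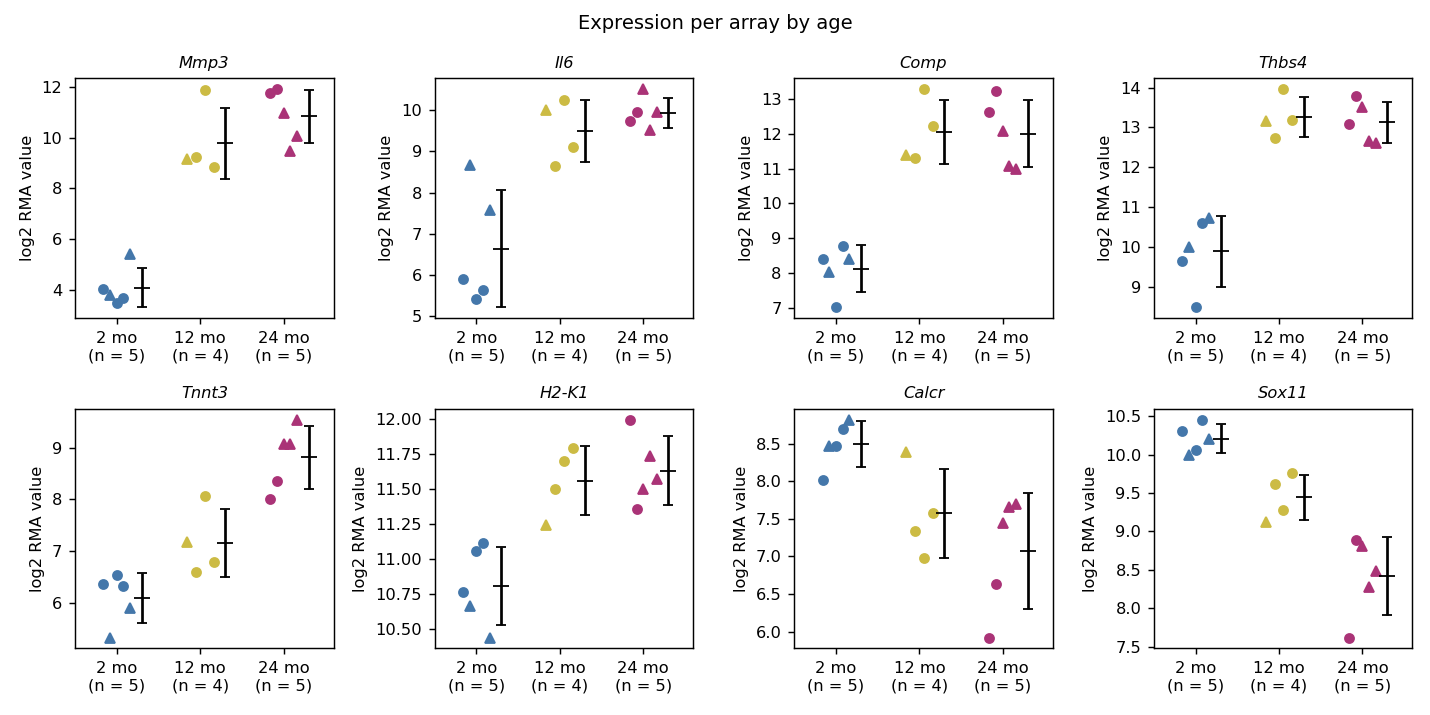
Log2 value (RMA) of 8 genes by age, 1 point per array (circles array set 1, triangles array set 2), with bars for mean ± SD (n = 5, 4 and 5). Mmp3, Il6, Comp and Thbs4 were already higher at 12 months, Tnnt3 went from 6.09 to 7.16 and 8.81, H2-K1 from 10.81 to 11.63, and Calcr and Sox11 from 8.49 and 10.21 to 7.07 and 8.42.

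Inflammatory secreted factors, interferon response and MHC class I presentation rose in aged cells, and all 3 calls held with an estimated correlation (adjusted p = 0.0167 for each). Of 17 inflammatory factors, 4 rose and 9 when adjusted over the list alone (adjusted p = 2.39e-08, median 0.79). Besides Mmp3 these were the cytokine Il6 (Entrez 16193, 9.80-fold, 3.29 ± 0.53), the eosinophil chemokine Ccl11 (9.55-fold, 3.26 ± 0.46) and the monocyte chemokine Ccl2 (5.80-fold, 2.54 ± 0.29). Young Il6 stood at 5.90, 5.42 and 5.63 on arrays 1, 3 and 4 (set 1) but at 8.67 and 7.58 on arrays 2 and 5 (set 2). Aged Il6 ran from 9.52 to 10.50, so the rise was smaller within set 2 and the fold averages both sets. Of 23 interferon response genes, 9 rose and 14 when adjusted over the list alone (adjusted p = 1.31e-13, median 0.79). Among them were the guanylate-binding protein Gbp2 (2.81-fold, 1.49 ± 0.28) and the antiviral membrane protein Ifitm1 (2.55-fold, 1.35 ± 0.25). In the 13-member MHC class I list, 6 genes rose and 8 when adjusted over the list alone, with 1 lower there (adjusted p = 4.76e-07, median 0.83). The immunoproteasome subunit Psmb8 rose 2.09-fold and the MHC transactivator Nlrc5 3.04-fold, and the near-identical heavy chain genes H2-K1 and H2-D1 rose 1.77-fold and 1.90-fold. Antioxidant and metallothionein genes rose less, with 4 of 23 past the test and 5 when adjusted over the list alone (adjusted p = 8.67e-05, median 0.25; adjusted p = 0.0167 with an estimated correlation). Sod2, the mitochondrial superoxide dismutase, rose 1.74-fold (0.80 ± 0.12) and the glutathione transferase Gstm2 1.81-fold (0.85 ± 0.16). The other members called were Mt1 and Mt2, and the antioxidant count was 2 without young array 1, 3 or 4 or aged array 1 or 4. The interferon count was 4 without young array 1 or 3, and the MHC class I count 4 without young array 3 or 4 or aged array 3. With the 3' minus 5' covariate 5 inflammatory, 3 interferon, 5 MHC class I and 1 antioxidant genes rose. Within array sets 1 and 2 the medians of these lists were 0.73 and 0.72 (inflammatory), 0.75 and 0.75 (interferon), 0.69 and 0.66 (MHC class I) and 0.15 and 0.35 (antioxidant). Within set 1 the calls of Psmb8 (adjusted p = 0.106), H2-K1 (0.111) and Gstm2 (0.108) were not reached. The 3' minus 5' covariate ended those of Gbp2 (1.29 ± 0.35, adjusted p = 0.0602) and Gstm2 (0.58 ± 0.17, 0.0747).

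Satellite cell identity genes fell in aged cells. Of 20 measured, 4 fell, 5 when adjusted over the list alone, and 0 rose (adjusted p = 0.000417, median -0.45; adjusted p = 0.0988 with an estimated correlation). These were Calcr (Entrez 12311), the calcitonin receptor found on quiescent satellite cells (2.67-fold lower, -1.42 ± 0.33), Fgfr4, a growth factor receptor of myogenic cells (2.37-fold, -1.24 ± 0.27), Dag1, which encodes dystroglycan (2.00-fold, from 12.11 to 11.11), and Chrdl2, an inhibitor of bone morphogenetic proteins (1.76-fold, -0.81 ± 0.19). The list median was -0.66 within set 1 and -0.25 within set 2. The call of Calcr ended without young array 3, 4 or 5 or aged array 2 (adjusted p = 0.0531 to 0.059), and that of Chrdl2 without young array 1, 3 or 4 or aged array 2, 3 or 5 (0.0507 to 0.0778) or within set 1 (0.135). With the 3' minus 5' difference as a covariate, the log2 changes of Dag1, Fgfr4 and Chrdl2 were smaller, their standard errors larger (-0.72 ± 0.25, -0.97 ± 0.33 and -0.66 ± 0.24). These calls ended (adjusted p = 0.127, 0.126 and 0.156), which left 1 member of the list, and 2 were left without young array 3 or 4 or aged array 2.

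Outside that list, the largest falls were those of Aard (3.64-fold, -1.86 ± 0.20) and Sox11 (Entrez 20666), a transcription factor of progenitor cells (3.45-fold, from 10.21 ± 0.19 to 8.42 ± 0.51). The receptor tyrosine kinase Ret fell 2.94-fold, the secreted protease Adamts20 3.18-fold and Nnt, the mitochondrial transhydrogenase, 2.87-fold. Foxred2, Ttyh1, Clmn, C1qtnf3, Lrrn1 and Reep1 fell 3.11-fold, 3.04-fold, 2.92-fold, 2.80-fold, 2.69-fold and 2.58-fold. Single arrays decided 3 of these calls: Nnt without young array 2, 3 or 5 or aged array 1 or 4 (adjusted p = 0.0655 to 0.0723), C1qtnf3 without young array 2, 3 or 5 or aged array 2 or 4 (0.0515 to 0.0819) and Reep1 without young array 1 or 4 or aged array 1 or 2 (0.0542 to 0.0649). With the 3' minus 5' covariate Lrrn1 and Reep1 kept log2 changes of -1.48 ± 0.39 and -1.35 ± 0.42 (-1.43 ± 0.30 and -1.37 ± 0.32 without it) but lost their calls through the larger errors (adjusted p = 0.0536 and 0.089). The call of Nnt was not reached within set 1 (0.199) or with array weights (-1.34 ± 0.38, 0.0601). Of the aged arrays, 3 for Reep1 and 2 for Lrrn1 lay below the 40th percentile, so these folds are imprecise.

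Transcripts of the mature myofibre, contractile and metabolic proteins of differentiated fibres, rose in aged cells. Of 19 measured, 12 rose, 13 when adjusted over the list alone, and 1 fell (adjusted p = 1.38e-14, median 1.60; adjusted p = 0.0900 with an estimated correlation). Myl1 (7.61-fold, 2.93 ± 0.44) and Mylpf (5.07-fold, 2.34 ± 0.30) encode myosin light chains, Tnnt3 (Entrez 21957, 6.61-fold, 2.73 ± 0.33) encodes fast troponin T and Eno3 (3.04-fold, 1.60 ± 0.24) muscle enolase. Actn3, the fast-fibre alpha-actinin, fell instead, from 10.90 to 9.91. The median was 0.84 within set 1 and 2.38 within set 2, and the calls of Myl1 and Eno3 were not reached within set 1 (adjusted p = 0.108 and 0.0712). Of 18 genes of myogenic commitment and fusion, by contrast, 1 rose (Cdh2, an adhesion protein, 2.22-fold) and 1 fell (Chrna1, a subunit of the acetylcholine receptor, 2.62-fold), with no call for the list (adjusted p = 0.270, median 0.11). Cdh2 lay below the 40th percentile on 3 young arrays, and it was not called with the 3' minus 5' covariate (0.89 ± 0.25, adjusted p = 0.0666). Without young array 1, 3 or 4 the call of Chrna1 ended (adjusted p = 0.0523 to 0.0585), as it did with that covariate (-1.05 ± 0.38, 0.147). S phase and mitosis genes were lower (21 measured, 1 fell, 3 when adjusted over the list alone, adjusted p = 0.0301, median -0.26; adjusted p = 0.342 with an estimated correlation). The member that fell was Cdc20, an activator of the anaphase-promoting complex (2.74-fold, -1.45 ± 0.33). Its call ended without young array 1 or 3 (0.0569 and 0.0548), without probe sets of shared sequence (-0.82 ± 0.30, 0.157) and with the 3' minus 5' covariate (-1.10 ± 0.40, 0.152). The list call ended without young array 1 or 4 or aged array 1 or 2 (0.0668 to 0.0937), without probe sets of shared sequence (0.123), with the covariate (median -0.18, 0.144) and with the array set as a term (0.0626). Within set 2 the S phase median was 0.05, against -0.53 within set 1.

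**Figure D3:**
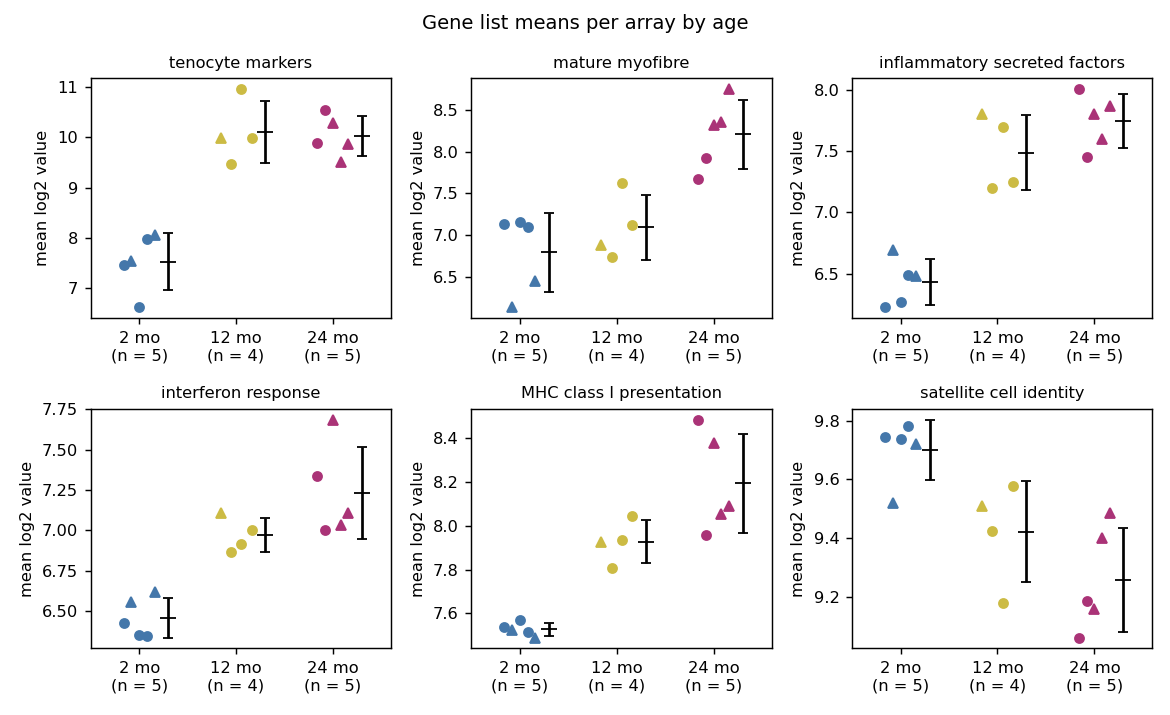
Mean log2 value of the measured genes of 6 lists on each array by age (circles array set 1, triangles array set 2), with bars for mean ± SD (n = 5, 4 and 5). The tenocyte mean went from 7.53 to 10.10 at 12 months, the mature myofibre mean from 6.80 to 7.09 and 8.21, and the satellite cell identity mean from 9.70 to 9.26 at 24 months.

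Markers of other cell types moved in smaller steps. The gate against CD45 is meant to remove macrophages, lymphocytes and neutrophils, and that against Sca-1 endothelial and fibro-adipogenic cells. None of the calls except that of the tenocyte list held with an estimated correlation. Fibro-adipogenic and fibroblast markers were higher (14 measured, 3 rose, 6 when adjusted over the list alone with 1 lower there, adjusted p = 0.00924, median 0.44; adjusted p = 0.342 with an estimated correlation). Dcn, the abundant matrix proteoglycan decorin, rose 2.40-fold (1.27 ± 0.18), while the fibroblast matrix gene Dpt had -0.46 ± 0.15 and did not pass. Pericyte and smooth muscle markers (12 measured, 1 rose, 3 when adjusted over the list alone) had an adjusted p of 0.0137 and adjusted p = 0.293 with an estimated correlation, and Pdgfrb, a growth factor receptor of mural cells and fibroblasts, rose 6.81-fold (2.77 ± 0.32). Schwann and glial markers (10 measured, 1 rose, 1 when adjusted over the list alone, median 0.41) had an adjusted p of 0.0152 and adjusted p = 0.342 with an estimated correlation. Adipocyte markers (5 measured, 1 rose, 2 when adjusted over the list alone, median 0.61) had an adjusted p of 0.0265 and adjusted p = 0.293 with an estimated correlation. Endothelial (adjusted p = 0.115), macrophage and myeloid (0.137), lymphoid (0.423) and neutrophil markers (0.998) were not called, but the endothelial mean reached 6.30 on aged array 3 and 5.60 on aged array 2, against 4.85 ± 0.23 on young arrays. The members called for Schwann and adipocyte markers, Scn7a and Fabp4, were not called with the 3' minus 5' covariate (1.01 ± 0.41, adjusted p = 0.204, and 2.11 ± 0.94, 0.250). Scn7a was also lost without young array 1, 3 or 4 or aged array 1, 2, 4 or 5 (0.0593 to 0.111), Fabp4 without young array 1, 2, 3 or 4 or aged array 2 or 5 (0.054 to 0.0938), and without young array 4 only 1 fibro-adipogenic marker rose. Single arrays ended these list calls: fibro-adipogenic without aged array 3 (adjusted p = 0.0576), pericyte without young array 4 or aged array 4 (0.0503 and 0.0941), Schwann without aged array 1 (0.0967) and adipocyte without aged array 3 or 5 (0.0714 and 0.0585). The 3' minus 5' covariate ended the pericyte (median 0.73 without and -0.02 with it, adjusted p = 0.766) and adipocyte (0.61 and 0.39, 0.166) calls. The array set as a term ended the adipocyte call (0.0626). Medians within sets 1 and 2 were 0.38 and 0.43 (fibro-adipogenic), 0.19 and 0.89 (pericyte), 0.72 and 0.25 (Schwann), 0.24 and 1.01 (adipocyte) and 2.68 and 2.17 (tenocyte).

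The remaining lists were not called in aged against young cells. Among signalling lists, JAK-STAT signalling had 4 of 19 members higher and 1 lower (adjusted p = 0.0700, median 0.10; 5 and 1 when adjusted over the list alone), among them the oncostatin M receptor Osmr (1.92-fold) and Stat6 (2.28-fold). Stat6 was not called within set 1 (adjusted p = 0.0558). Osmr was not called with the mean of its probe sets (0.49 ± 0.16, adjusted p = 0.0914) or with the 3' minus 5' covariate (0.71 ± 0.19, 0.0606). TGF-beta family ligands, receptors and SMADs had 1 of 33 higher, the activin and myostatin antagonist Fst (4.42-fold, 2.14 ± 0.44), 2 when adjusted over the list alone (adjusted p = 0.0859). The 3' minus 5' covariate took the change of Fst to 1.22 ± 0.41 (adjusted p = 0.121). The Notch pathway (20 measured, adjusted p = 0.0897), FGF and MAPK signalling (21, 0.998) and the Wnt pathway (22, 0.734) had 1, 1 and 2 members higher and 0 lower. The Notch member, Rbpj, was not called in 10 of 14 single-array omissions (0.0523 to 0.118, all but those of young array 2, middle-aged arrays 1 and 2 and aged array 1), nor with the mean of its probe sets (0.29 ± 0.14, 0.295). These lists had 1, 1 and 2 higher and 3, 2 and 1 lower when adjusted over the list alone. Among metabolic lists, glycolysis (13 measured, 0.121), oxidative phosphorylation (32, 0.265) and autophagy and lysosome genes (22, 0.697) had 0, 0 and 1 higher and 0, 0 and 1 lower. Adjusted over the list alone 5, 0 and 1 were higher and 1, 0 and 1 lower, and Ldha, lactate dehydrogenase A, had 0.61 ± 0.17 without passing (adjusted p = 0.0517). Adjusted p was 0.236 for quiescence regulators, 0.825 for cell cycle inhibitors and p53 targets, 0.380 for DNA repair, 0.485 for the unfolded protein response and chaperones, 0.265 for collagens and matrix, 0.620 for dissociation and immediate early genes, 0.734 for ribosomal proteins, 0.111 for Hox genes and 0.121 for chromatin modifiers. Median, mean and test differed in sign for cell cycle inhibitors (-0.10, 0.08, up), Wnt (-0.08, 0.05, up), FGF and MAPK (-0.02, 0.01, down), collagens (-0.12, 0.24, up) and neutrophil markers (-0.01, 0.06, down).

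In all, limma called 584 of 13579 genes in aged against young cells at an adjusted p under 0.05, 414 higher and 170 lower, 352 of them by more than 2-fold, and 2252 genes had an unadjusted p under 0.05, where chance gives 679. The count of falls depended on single arrays, with 87 without young array 1 or without young array 3 and 93 without young array 4. These are the young arrays of set 1. Without young array 2 or 5, those of set 2, it was 170 and 154. Rises and falls numbered 276 and 186 with the 3' minus 5' covariate, 395 and 307 within set 1, and 79 and 11 by an unequal-variance test per gene. The groups did not overlap for 473 of the 584, and for 5.45% of all genes, where chance gives 0.794%. All 584 changed the same way within both array sets, and with the set as a term 976 genes were called, all 584 among them. The 584 were called on these same arrays and the sets defined from the same values, so neither result is independent support. Within set 1 alone (3 against 2 arrays) 702 were called, and within set 2 alone (2 against 3) 21. Without young array 3 the total was 388, and the unequal-variance test called 90. With the tenocyte marker mean of each array as a covariate, 86.9% of whose variance lay between ages, 0 genes were called (722 at an unadjusted p under 0.05): the median size of the 584 log2 changes went from 1.15 to 0.73 and their median standard error from 0.235 to 0.544. Prg4, Itgbl1, Cpxm2 and Tnmd turned direction under it (-0.10, -0.0725, -0.12 and -0.27, none called), Tnmd by construction as 1 of the markers in the covariate.

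**Figure D4:**
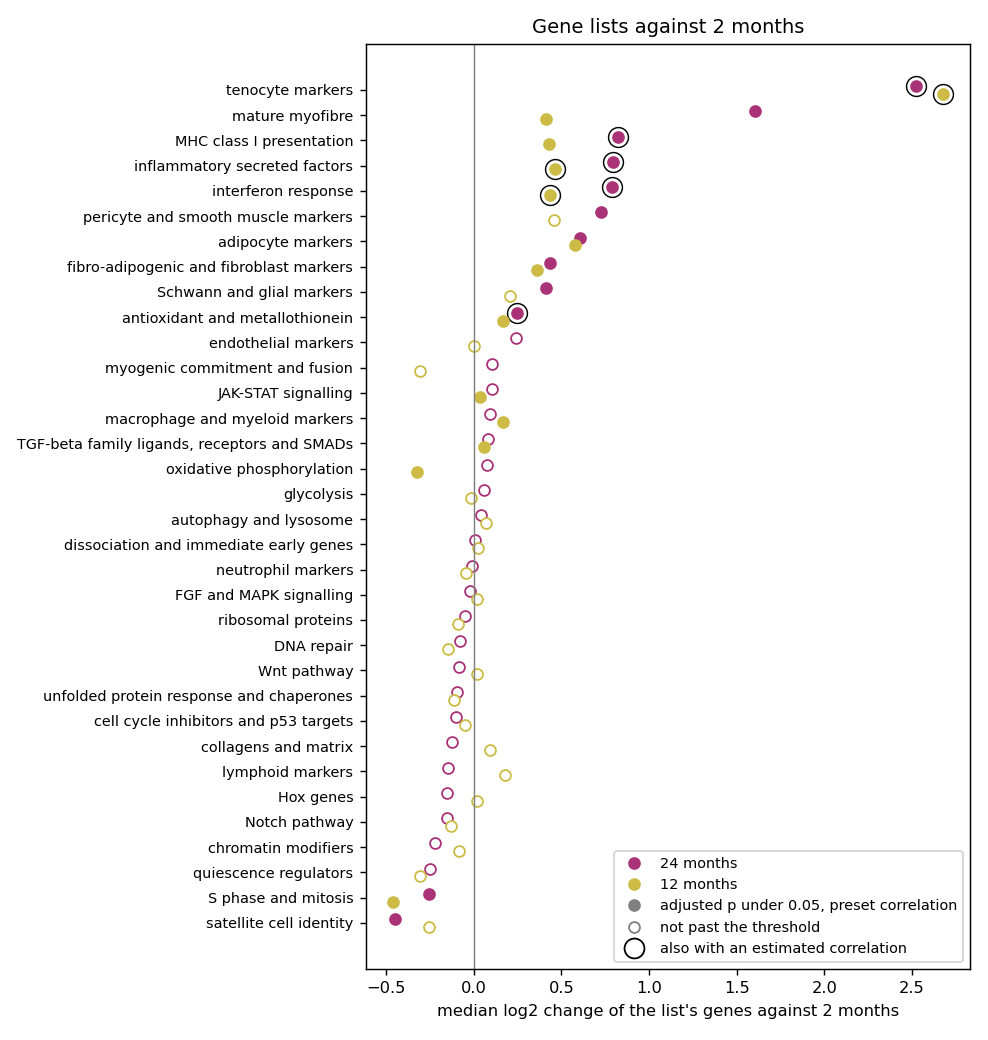
Median log2 change of the genes of 34 lists at 24 months (purple) and 12 months (yellow) against 2 months, filled where camera with a preset correlation gave an adjusted p under 0.05 and ringed where the call held with an estimated correlation. Tenocyte markers lie farthest right (2.52 and 2.68), and satellite cell identity lies lowest at 24 months (-0.45).

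Middle-aged against young cells asked whether these differences were present by 12 months. Tenocyte markers and inflammatory factors had already risen, and the cell division gene Cdca8 and the acetylcholine receptor gene Chrna1 fell. Tenocyte markers rose as a group with 8 of 9 members past the test, also when adjusted over the list alone (adjusted p = 1.28e-18, median 2.68; adjusted p = 0.0435 with an estimated correlation), and their medians within sets 1 and 2 were 2.80 and 2.40, the latter from 1 middle-aged array. Comp rose 15.2-fold (3.92 ± 0.50, n = 4 against 5), Thbs4 10.3-fold (3.37 ± 0.40) and Chad, the cartilage protein chondroadherin, 10.8-fold (3.43 ± 0.45). Prg4, Aspn and Cilp rose 14.4-fold, 13.7-fold and 13.1-fold, and Mmp3 51.8-fold (5.70 ± 0.62). The protease inhibitor Serpina3n rose 10.9-fold (3.45 ± 0.38), Angptl7, a secreted angiopoietin-like protein, 11.9-fold, Ccdc3 10.3-fold, Cpxm2 10.2-fold and Mndal 11.5-fold, the last not called without probe sets of shared sequence (adjusted p = 0.0703).

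The falls at 12 months were led by Cdca8, a subunit of the chromosomal passenger complex of mitosis (7.77-fold, -2.96 ± 0.56), and Chrna1 (4.53-fold, -2.18 ± 0.33). Slc11a2, an iron transporter, fell 3.08-fold, Dbp, a clock-controlled transcription factor, 2.90-fold, and Aard, Lrrn1 and Snhg4 3.36-fold, 3.08-fold and 2.83-fold. Of the 4 middle-aged Lrrn1 values 3 lay below the 40th percentile, so that fold is imprecise. Falls of C1qtnf3, Crot, Adamts20, Itm2a and Pde1c (3.07-fold, 2.99-fold, 2.77-fold, 2.73-fold and 2.72-fold) rested on single arrays. The call of Adamts20 ended without middle-aged array 2, 3 or 4 (adjusted p = 0.0502 to 0.0689), that of Itm2a without any of young arrays 1, 3 and 4 and middle-aged arrays 2, 3 and 4 (0.0536 to 0.0837), and that of Crot, for which only 1 of 2 probe sets fell, without any of young arrays 2 to 5 and middle-aged arrays 2, 3 and 4 (0.0523 to 0.105). The call of C1qtnf3 ended without any of the 5 young arrays or middle-aged array 1, 3 or 4 (0.0551 to 0.119), and that of Pde1c without any of the 5 young arrays or middle-aged array 2, 3 or 4 (0.0526 to 0.105). Slc11a2 and Pde1c were not called with the mean of their probe sets (-0.71, adjusted p = 0.0534, and -0.50 ± 0.19, 0.193), nor Dbp without probe sets of shared sequence (-1.01, 0.0982).

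S phase and mitosis genes fell as a list at 12 months (21 measured, 1 fell, also when adjusted over the list alone, adjusted p = 0.00599, median -0.46; adjusted p = 0.289 with an estimated correlation). The member was Cdc20 (2.71-fold), whose call ended without young array 1, 3 or 4 or any middle-aged array (0.0735 to 0.0952), with the 3' minus 5' covariate (-1.23 ± 0.37, 0.0671), with the mean of its probe sets (-0.90 ± 0.27, 0.0905) and without those of shared sequence (-0.92 ± 0.31, 0.152). Within set 2, which holds 1 middle-aged array, the list median was -0.02 and the call was not reached (0.426), which rests on that array. Oxidative phosphorylation was called lower although 0 of its 32 members passed, also when adjusted over the list alone (adjusted p = 0.000147, median -0.33; adjusted p = 0.289 with an estimated correlation). Cox5b, a subunit of cytochrome c oxidase, had -0.36 ± 0.12, and the list call was likewise not reached within set 2 (0.170). Satellite cell identity had a median of -0.25 and 0 of 20 members past the test, 2 lower when adjusted over the list alone (adjusted p = 0.0714).

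Inflammatory factors and interferon response were called higher at 12 months, and both calls held with an estimated correlation (adjusted p = 0.0435 for each). Il6, Ccl11, Ccl2 and Mmp3 rose among 17 inflammatory genes, also when adjusted over the list alone (adjusted p = 6.74e-07, median 0.46), Ccl2 by 4.23-fold (2.08 ± 0.30) and Il6 by 7.26-fold (2.86 ± 0.56). The groups overlapped for Il6, with 8.67 on young array 2 and 8.64 on middle-aged array 2. Of 23 interferon genes 2 rose, 4 when adjusted over the list alone (adjusted p = 3.6e-08, median 0.43), with Gbp2 at 3.50-fold. MHC class I presentation had 3 of 13 higher, 6 when adjusted over the list alone (adjusted p = 0.000797, median 0.43; adjusted p = 0.0819 with an estimated correlation). JAK-STAT signalling had 4 of 19 higher, 5 when adjusted over the list alone (adjusted p = 0.00913, median 0.04; adjusted p = 0.0819 with an estimated correlation), among them Osmr (2.16-fold, not called with the mean of its probe sets, 0.144) and Stat5a (1.67-fold). Antioxidant genes (23 measured, 1 rose, 3 when adjusted over the list alone) had adjusted p = 0.0225 and adjusted p = 0.170 with an estimated correlation, with Sod2 at 1.77-fold. The MHC class I members were H2-D1, H2-K1 and Tapbp, and 0 of them were called without young array 2 or 5 or middle-aged array 2, 3 or 4. Without middle-aged array 3, 2 inflammatory and 2 JAK-STAT genes were called, and 1 interferon gene without young array 1, 3 or 4 or middle-aged array 3 or 4. Of the inflammatory members, Il6 was not called without middle-aged array 3 (0.0577) and Ccl11 without young array 1, 3 or 4 or middle-aged array 1, 3 or 4 (0.0513 to 0.0628). The antioxidant call ended without young array 4 (0.0527) or middle-aged array 1 (0.0534), and the 3' minus 5' covariate ended the JAK-STAT (median 0.03, 0.0642) and antioxidant (median 0.13, 0.113) calls.

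A further 5 lists were called higher at 12 months, none with an estimated correlation. Fibro-adipogenic and fibroblast markers (adjusted p = 0.00913; adjusted p = 0.469 with an estimated correlation) had 1 of 14 members higher, also when adjusted over the list alone, Dcn (2.70-fold, 1.43 ± 0.19). TGF-beta family genes (33 measured, adjusted p = 0.0333; adjusted p = 0.231 with an estimated correlation) had 0 members past the test, also when adjusted over the list alone, with Bmp4 at 0.62 ± 0.22. Mature myofibre genes (adjusted p = 0.0359, median 0.41; adjusted p = 0.618 with an estimated correlation) had 0 of 19 higher and 1 lower, also when adjusted over the list alone, Actn3 (2.48-fold). Macrophage and myeloid markers (adjusted p = 0.0360; adjusted p = 0.232 with an estimated correlation) had 1 of 12 higher, also when adjusted over the list alone, the lipopolysaccharide co-receptor Cd14 (2.46-fold), a call that ended without middle-aged array 3 or 4 (0.0655 and 0.0651). Adipocyte markers (adjusted p = 0.0422; adjusted p = 0.385 with an estimated correlation) had 0 of 5 members higher, 3 when adjusted over the list alone. Single arrays ended the myofibre call (young 2 or 5 or middle-aged 3, 0.110 to 0.269), the TGF-beta call (young 1 or 4 or middle-aged 1, 0.0581 to 0.118), the macrophage call (young 2 or 4 or middle-aged 2 or 3, 0.0541 to 0.0728) and the adipocyte call (young 1, 2, 3 or 4 or middle-aged 1 or 4, 0.0564 to 0.146). The 3' minus 5' covariate ended the TGF-beta (median 0.07, 0.265), myofibre (0.37, 0.0831) and adipocyte (0.71, 0.158) calls. The array set as a term ended the myofibre (0.0757) and macrophage (0.0584) calls.

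In total limma called 403 genes at 12 months, 237 higher and 166 lower, and 2217 had an unadjusted p under 0.05. The balance of directions was not stable: 186 were higher and 221 lower without middle-aged array 1, 361 and 380 with the array set as a term, 334 and 630 within set 1, 301 and 416 with the 3' minus 5' covariate, and 496 and 657 with array weights. Other omissions moved it toward rises, with 247 and 84, 123 and 32, and 137 and 50 without middle-aged array 2, 3 or 4. Without young array 1 or 3 it was 150 and 59, and 149 and 59. The groups did not overlap for 371 of the 403, and for 8.70% of all genes, where chance gives 1.59%. With the set as a term 741 genes were called, all 403 among them, and 964 were called within set 1, while within set 2, where 1 middle-aged array stood against 2 young arrays and was assumed to vary like the others, 0 were called. The count was 209, 208 or 234 without young array 1, 3 or 4, 155 without middle-aged array 3 and 187 without middle-aged array 4, 4 by an unequal-variance test per gene, and 0 with the tenocyte covariate (484 at an unadjusted p under 0.05), under which Chad, a member of the covariate, and Cpxm2 turned direction (-0.11 and -0.27, not called).

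Aged against middle-aged cells covered the late step. Mature myofibre genes were called higher as a list (19 measured, adjusted p = 1.8e-15, median 1.25; adjusted p = 0.190 with an estimated correlation), with 0 members past the test over all genes and 14 when adjusted over the list alone. Tnnt3 had 1.66 ± 0.35, Tnnc2, fast troponin C, 1.62 ± 0.36 and Ckm, muscle creatine kinase, 1.51 ± 0.33 (n = 5 against 4). Oxidative phosphorylation was called higher (32 measured, 0 past the test, 5 when adjusted over the list alone, adjusted p = 2.85e-09, median 0.31; adjusted p = 0.190 with an estimated correlation), with Ndufs3, a subunit of complex I, at 1.02 ± 0.20. Myogenic commitment and fusion was called higher (18 measured, 0 past the test, 0 when adjusted over the list alone, adjusted p = 0.000323, median 0.61; adjusted p = 0.195 with an estimated correlation), with Mef2c, a myogenic transcription factor, at 1.16 ± 0.37. Hox genes, which encode positional transcription factors, were called lower (18 measured, 0 past the test, 0 when adjusted over the list alone, adjusted p = 0.00224, median -0.21; adjusted p = 0.190 with an estimated correlation), and Hoxa3 had -0.29 ± 0.12. Tenocyte markers had a median of -0.09 in this step (adjusted p = 0.700). Within sets 1 and 2 the medians were 0.59 and 1.78 (myofibre), 0.19 and 0.27 (oxidative phosphorylation), 0.47 and 0.57 (commitment) and -0.16 and -0.13 (Hox), the Hox call being lost within set 2 (0.102). The values within set 2 rest on 1 middle-aged array.

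For single genes of the late step, limma called 0 of 13579 and an unequal-variance test per gene also 0. The smallest adjusted p was 0.242, and 1306 genes had an unadjusted p under 0.05, where chance gives 679. The 5 genes with the smallest p, none of which passed, were Aar2 (1.45 ± 0.24), Enho (0.79 ± 0.14), Med8 (0.83 ± 0.15), Borcs7 (0.86 ± 0.17) and Ndufs3 (1.02 ± 0.20). The groups did not overlap for 2.50% of genes, where chance gives 1.59%. Without aged array 4, 8 lists were called in place of 4.

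Changes at 12 and at 24 months were compared across genes. Of the genes called at both ages, 197 were higher in both (7.23 by chance if independent), 59 were lower in both (2.08) and 0 had opposite directions. The log2 changes had a Pearson r of 0.771 across 13579 genes, which are not independent replicates. Both contrasts share the young arrays, and simulated groups without any effect gave 0.471 (0.436 to 0.498 over 100 simulations). The simulations drew every gene and array independently and held no array sets, so chance can range more widely on the real arrays. With the young arrays split so that each contrast had its own, the mean r over 20 splits was 0.589 (0.338 to 0.693). Comp is an example of a gene at its later level by 12 months (8.12, 12.05 and 12.00), and Sox11 had intermediate values there (10.21, 9.44 and 8.42).

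Whether the late step differed from the early one was tested directly. By limma 0 genes differed, with 1614 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0967, and 1 gene was called without middle-aged array 1 or without middle-aged array 2. With array weights 179 genes differed, 123 higher and 56 lower. With the array set as a term 7 genes differed, among them Slc11a2 (late minus early 2.39 ± 0.28, adjusted p = 0.00666) and Serpina3n (-3.60 ± 0.56, adjusted p = 0.0397). That term was defined from these same values, so its adjusted p can be too small. Camera called 9 lists, 4 with a higher and 5 with a lower late minus early value, and 0 of them held with an estimated correlation (smallest adjusted p = 0.232). Tenocyte markers had the largest difference, with a median of -2.83 (adjusted p = 1.14e-11; adjusted p = 0.232 with an estimated correlation), and oxidative phosphorylation the smallest p among the 4 higher lists (median 0.63, adjusted p = 1.46e-08; adjusted p = 0.232 with an estimated correlation). The list call count was 5 without middle-aged array 1 or without middle-aged array 2. A moderated F test over the 3 ages called 565 genes (2430 at an unadjusted p under 0.05), and 306, 282 or 317 without young array 1, 3 or 4.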

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

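The tests of explanations and the splits of the arrays in this part were set up only after the results were seen.

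Tenocyte markers stood higher at 12 and 24 months than at 2 months, by a mean log2 of 2.56 and 2.49. A lower share of the main cell type would raise the markers of all other types alike. Well-measured markers of other types (32 genes) changed by 0.50 at 24 months, 1.98 less than the tenocyte markers (exact permutation p = 0.00794, 252 arrangements). These 32 genes were kept for lying above the 60th percentile on every young array, a filter not put on the tenocyte markers. Genes so high in young sorted cells may come from the main cell type, so the comparison cannot decide and this explanation stays open. The array sets are argued against, since the median change was 2.17 within set 2 and 2.68 within set 1 (exact permutation p = 0.01 with arrays exchanged only within the sets). A larger share of tendon cells in the sort may contribute and stays open. Within an age the 9 markers varied together (mean correlation 0.586, where 95% of 10000 random lists lay below 0.137 and the highest reached 0.498). Markers picked for 1 cell type can also vary together through a change within the precursor cells. The deviations also kept the array sets, so this cannot decide. Of the abundant tendon collagens, Col1a2 had means of 11.69, 13.13 and 12.55 at 2, 12 and 24 months and Col1a1 9.57, 9.66 and 9.04. The mean change of both at 24 months was 0.17 (exact permutation p = 0.746), so a rise of both was not seen there. A high young level alone does not hide a change, since Fmod rose from young values of 11.52 to 13.05 to aged values of 13.99 to 14.55. Of the 9 markers, 6 lay above the filter on every young array and 0 belong to another list, the gate for CD29, Cxcr4 and against Sca-1 was not tested for tendon cells, and a change with age within the precursor cells stays open, as untested.

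Mature myofibre transcripts stood higher at 24 than at 2 months, by a mean log2 of 1.41. The commitment and fusion genes changed by 0.10, 1.31 less (exact permutation p = 0.00794), so the 2 lists did not rise together over this range. Commitment genes mark early steps and need not rise in cells past them, so this cannot decide on cells further along in differentiation. Such cells may contribute in the step from 12 to 24 months. There the myofibre mean changed by 1.11 and the commitment mean by 0.59 (exact permutation p = 0.0159), 0.52 less (exact permutation p = 0.143). Against 2 months the commitment list had a median change of -0.30 at 12 and 0.11 at 24 months. Its late rise was thus largely a return to the young level from a low on the 4 middle-aged arrays, so it cannot decide either. The array sets are argued against as the whole cause: the median change was 0.84 within set 1, 2.38 within set 2 and 1.64 with the set as a term (camera adjusted p = 1.01e-12). With arrays exchanged only within the sets the exact permutation p was 0.01, the smallest that 100 arrangements allow, so only the size of the change differed between sets. RNA or fragments of fibres carried through the sort may contribute and cannot be told apart from a change in the cells. Within an age the transcripts varied together (mean correlation 0.471, where 95% of random lists lay below 0.0896 and the highest reached 0.275). Genes picked for 1 tissue can vary together from either source, and the deviations kept the array sets, so this cannot decide between them. Atp2a1, Pygm and Actn3, also abundant in fast fibres, went from 7.57 to 7.84, 6.63 to 6.69 and 10.90 to 9.91, a mean change of -0.22 (exact permutation p = 0.516). They were picked after the results were seen, from a list in which 12 of 19 genes were called higher and only Actn3 lower. Actn3 alone makes that mean negative, so these genes decide nothing about fibre RNA. Of the 19 transcripts, 18 lay above the filter on every young array, and an effect of age itself stays open, as untested.

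The arrays parted into sets that crossed the ages. A different hybridization run is a candidate explanation: the hybridization controls, which are added after labelling, differed by -0.72 between set 2 and set 1 at equal age (exact permutation p = 0.0025, the smallest that 400 arrangements allow). A difference in RNA integrity may also be involved, since the 3' minus 5' difference of the control probe sets differed by -0.63 (exact permutation p = 0.015). The labels give no date or batch, and no biological explanation was tested.

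Other splits of the same arrays into groups of the same sizes were counted, 100 for each result. For aged against young, 2 of 100, the real split included, gave as many genes as the real 584, so few splits of these arrays gave so large a count. The labels do not say whether each array came from a separate animal, so the splits cannot exclude chance differences between animals. The higher split, with 772 genes and 2 lists, was the one that follows the array sets, which points to that structure of the samples; with the set as a term 976 genes were called, all 584 among them, and within set 2 alone 21. For middle-aged against young, 1 of 100 gave as many as the real 403 (highest other 14), and for the F test 1 of 100 as many as 565 (highest other 2). The same limit holds for both, and the 403 fell to 155 without middle-aged array 3. For aged against middle-aged and for the late minus the early step the real count was 0, so that 100 of 100 splits gave as many whatever the arrays, and the splits decide nothing there. The highest other of the late minus the early step was 3, and that of aged against middle-aged, 1614 genes, was the split of these 9 arrays that follows the sets (middle-aged 2, 3 and 4 with aged 1 and 2 against the rest), a structure of the samples; with the set as a term limma called 0 genes. For counts of lists, 1 of 100 gave as many as 13 at 12 months against 2 (highest other 12), with 126 splits possible. The margin was 1 list, with splits made only at the reported settings. There the 3' minus 5' covariate gave 9 lists and fry 8, so chance is not excluded for this count. For aged against young 8 of 100 gave as many as 12 (highest other 13), and for aged against middle-aged 63 of 100 as many as 4 (highest other 12). Chance cannot be excluded for these list counts either.

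Of 375 groups of arrays examined for the named genes and list means, 28 held 1 array far from the others, where chance gives about 18.8 (1 in 20). Middle-aged array 2 stood apart in 6, for Nnt (6.62), Gstm2 (6.07), Itgb1 (8.95), Stat6 (5.64), Atp5c1 (10.43) and Uqcrb (12.04). Middle-aged array 3 stood apart in 5, for Mmp3 (11.87), Fmod (14.53), Mylpf (8.78), Col1a2 (13.86) and Scx (5.40). Middle-aged array 1 did so for Aard (4.58), Clmn (8.91) and Itm2a (10.93). Young array 2 did so for Ccl2 (7.35), Sod2 (11.50) and the mean of the satellite cell identity list (9.52), young array 5 for Mmp3 (5.41) and Fabp4 (6.51), young array 3 for Cpxm2 (5.77) and Myl1 (6.77), and young array 1 for Mef2c (5.95). Aged array 1 did so for Sod2 (12.33) and Atp5c1 (10.78), aged array 3 for Mfap5 (8.07) and Fabp4 (11.10), and aged array 4 for Foxred2 (7.24) and Ldha (10.62).

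The late step differed from the early step for 9 lists by camera with a preset correlation and for 0 with an estimated one (smallest adjusted p = 0.232). The median late minus early differences were 0.95 for myogenic commitment and fusion, 0.76 for mature myofibre, 0.62 for S phase and mitosis and 0.63 for oxidative phosphorylation, and -0.29 for inflammatory secreted factors, -0.23 for interferon response, -0.23 for JAK-STAT signalling, -0.22 for Hox genes and -2.83 for tenocyte markers. Probe sets without a gene name also differed with age: of 4307 tested by limma, 37 were called in aged against young, 49 in middle-aged against young and 0 in aged against middle-aged cells.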

How the results depend on the processing

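The array sets, the tenocyte covariate and the list test of the late minus the early step were chosen only after the data were seen, and the cause of the differences below was not tested unless given. For total counts, the dim filters, both alternative choices of probe set, median centring, trended variance, the fold minimum and fits of only the groups compared gave values within 1.5 times the reported ones. Counts of rises and falls taken apart were not held to this limit, and some moved further. Leaving out each array in turn gave 388 to 608 genes for aged against young, 155 to 458 for middle-aged against young, 0 to 0 for aged against middle-aged, 282 to 603 for the F test and 0 to 1 for the late minus the early step. The same omissions gave 10 to 15, 10 to 14, 4 to 8 and 5 to 10 lists for the 4 contrasts, and r from 0.697 to 0.794. Array weights gave 1153 genes for middle-aged against young, 179 for late minus early and 1007 by the F test. The 3' minus 5' covariate gave 717 for middle-aged against young, and a block by replicate number 194, with 341 by the F test, although the numbers do not pair the samples (correlations of same-numbered arrays from -0.484 to 0.261). The unequal-variance test, which estimates each gene's spread from its own arrays, gave 90 for aged and 4 for middle-aged against young. Quantile normalization called 7 lists in aged against middle-aged. An estimated correlation called 5, 3, 0 and 0 lists in the 4 contrasts, and fry 8 for middle-aged against young, 2 for aged against middle-aged and 2 for late minus early. The array set term gave 976 and 741 genes for aged and middle-aged against young, 7 for late minus early and 974 by the F test. Set 1 alone gave 964 for middle-aged against young and 7 lists for aged against middle-aged, and set 2 alone, with fewer arrays, 21 and 0 genes against young, 7 by the F test and r = 0.643.

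With the tenocyte covariate, limma called 0 genes for aged against young (722 at an unadjusted p under 0.05), 0 for middle-aged against young (484) and 0 by the F test. The covariate shares 86.9% of its variance with age, so standard errors went from a median of 0.235 to 0.544 in aged against young, and 516 of 584 genes kept their direction. Reversed under it, none past the threshold, were Prg4 (-0.10), Itgbl1 (-0.0725), Cpxm2 (-0.12), Dkk3 (-0.0667), Tnc (-0.61) and Tnmd (-0.27) at 24 months, and Chad (-0.11) and Cpxm2 (-0.27) at 12 months. Tnmd and Chad are among the 9 markers that make up the covariate, which removes their change by construction. Of 123 calls for single named genes, 89 survived every single-array omission, 94 the 3' minus 5' covariate and 123 the array set term. Other settings ended 18 (set 1 alone), 113 (set 2 alone), 18 (replicate block), 11 (mean of probe sets), 10 of 119 (without probe sets of shared sequence) and 6 (no dim filter) of them, and 2 or fewer each for array weights, median centring, quantile normalization, trended variance and the stricter dim filter. The tenocyte covariate kept 0 of the 123, and the unequal-variance test, the fold minimum and fits of only the groups compared were run for counts alone. At least 3 arrays of 1 group lay below the 40th percentile for Mmp3, Mndal, Aspn, Scx and Cdh2 (young), Lrrn1 (middle-aged) and Reep1 (aged), so that their folds are imprecise.

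List calls were kept in fewer than 27 of 27 settings, single omissions included, for S phase (19), adipocyte (20), pericyte (23), fibro-adipogenic (25) and Schwann markers (25) in aged against young. At 12 months against 2 they were kept in 16 for macrophage, 17 for adipocyte, 20 for myofibre, 22 for TGF-beta, 22 for antioxidant and 26 each for S phase, JAK-STAT and oxidative phosphorylation. In aged against middle-aged Hox was kept in 26, and for late minus early interferon and Hox were kept in 14 each, S phase in 20, myofibre in 24, JAK-STAT in 25 and inflammatory factors in 26. The 12-month myofibre call ended with array weights (adjusted p = 0.0879) and the macrophage call with no dim filter (0.104), the mean of probe sets (0.0505), no probe sets of shared sequence (0.0657) and quantile normalization (0.0644), which also ended the adipocyte call (0.0644).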

Other observations

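The array set term and the tests of Scin and Ccdc12 were chosen only after the results were seen.

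Several single genes changed with age whose lists were not called. Timp1, a secreted inhibitor of metalloproteases, rose 5.67-fold from 2 to 24 months (2.50 ± 0.20, n = 5 against 5), Timp3 2.33-fold (1.22 ± 0.22) and Tnc, the matrix protein tenascin C, 4.98-fold (2.32 ± 0.40), while Col15a1, a basement membrane collagen, fell 2.46-fold (-1.30 ± 0.22). Within the collagens and matrix list, 4 of 24 members rose and 2 fell, 6 and 3 when adjusted over the list alone. The count of falls was 1 without young array 1, 3 or 4 or aged array 1 or 5. The count of rises was 3 without young array 1 or 4 or aged array 2 or 3. With the 3' minus 5' covariate 3 rose and 1 fell. Dkk3, a secreted Dickkopf family protein, rose 3.28-fold (1.71 ± 0.33), and the stress kinase Mapk12, also known as p38 gamma, rose 3.25-fold (1.70 ± 0.31). Among cell cycle inhibitors and p53 targets, Gadd45g, a stress-induced growth arrest gene, rose 2.46-fold (1.30 ± 0.20) and Perp, a p53 target, 3.79-fold (1.92 ± 0.40). That list also had 1 member called lower, and 0 without young array 1, 3 or 4, among other omissions. The orphan nuclear receptor Nr4a2 rose 2.45-fold, while the other immediate early genes of the dissociation list, of which 23 were measured, did not pass, 1 having risen also when adjusted over the list alone. Among quiescence regulators the chemerin gene Rarres2 rose 1.90-fold, while 1 other member was called lower. With the 3' minus 5' covariate 0 members of either list were lower. The 3' minus 5' covariate ended the calls of Perp (1.27 ± 0.43, adjusted p = 0.124) and Rarres2 (0.73 ± 0.21, 0.0765), and the tenocyte covariate those of all genes named in this paragraph, with Tnc at -0.61 and Dkk3 at -0.0667 turned in direction. Without probe sets of shared sequence, the calls of Nr4a2 (0.164) and Rarres2 (0.879) ended, and within set 1 those of Gadd45g (0.0848), Rarres2 (0.114) and Mapk12 (0.142) were not reached.

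With the array set as a term, the late step differed from the early step for Slc11a2 (2.39 ± 0.28), Borcs7 (1.89 ± 0.30), Ccdc12 (1.85 ± 0.29) and Med8 (1.55 ± 0.25), and for Serpina3n (-3.60 ± 0.56), Scin (-2.95 ± 0.43) and Ccl11 (-2.05 ± 0.33), with adjusted p from 0.00666 to 0.0441. Of these genes all but Ccl11 had their highest or lowest mean at 12 months. Slc11a2, the iron transporter, had means of 8.12, 6.50 and 7.03 at 2, 12 and 24 months, and Med8, a Mediator subunit, 8.19, 7.39 and 8.22. Scin, an actin-severing protein, had 4.67, 7.04 and 6.72, so that its rise lay before 12 months. Without the set term 0 of these differences passed by limma. The sets were defined from the spread of these same values within ages, which the term then takes out, so these adjusted p can be too small.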
